A study of Mus musculus with 24 samples.

How the data were processed

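RNA from kidney tissue of 24 C57BL/6J mice aged 10 weeks, an inbred laboratory strain, was sequenced after selection of polyadenylated RNA, per the labels' protocols, with 1 library per mouse. The groups were 6 females with free access to water, 5 females without water, 6 males with free access to water and 7 males without water. Water was withheld for 9 to 11 h, and kidneys were collected within 1 h of midnight, 6 h into the active period of the animals, per the labels, though the clock time they give for taking the water away does not fully match these hours. Groups were taken from the titles. The title and the library code of deprived female 5 place it among the deprived females, whereas its treatment label describes free access, so it was kept with the deprived females and counted with the other group in an alternative.

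The authors deposited a single table of normalized gene counts, a signal on a linear scale, with 19399 genes in 24 columns. The submitters' processing notes name Trim Galore, featureCounts of Subread, DESeq2 and the mm10 build, without versions. The aligner, the annotation release and the use of strand in counting are not given in the sources used here. Of the values deposited in each column, 100.0% came out within 0.01 read of a whole multiple of 1 step, so that whole reads were recovered by removing 1 size factor per library. The size factors equalled those that the median-of-ratios method of DESeq2 gave on the recovered reads, with a largest relative difference of 1.9e-15. The smallest total of a gene was 100 reads and each gene had a read in at least 12 libraries, so genes with few reads were absent from the table before the work described here. The recovered reads summed to between 14411843 and 29398960 per library. Gene names came from the table where it gave usable ones and otherwise from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, in which 19298 of the gene identifiers had a match. Coordinates are 1-based and from that annotation. A total of 23 names had been turned into dates in the table and were replaced from the annotation through the gene identifier.

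The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with the pseudocount of 1, 1 coefficient per group, a trended and robust prior variance, and a single fit of all 24 libraries. Fold changes are on this log2(value + 1) scale, which understates the change of genes with low values. Genes with a value of at least 10 in at least 5 libraries were tested, which kept 17592 genes and left out 1807. The p-values were adjusted by the Benjamini-Hochberg method over the tested genes and called below 0.05. The contrasts were deprived against watered mice in females, in males and as the mean of both sexes, the male minus the female response, and males against females in each water group. The responses of the sexes were also compared by the Pearson and Spearman correlation of their log2 changes across genes, which are not independent replicates, and by the number of genes called in both. The comparisons in the sexes share no library, though they share 1 estimate of the spread per gene.

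A total of 38 gene lists, among them markers of the cell types of the kidney and of neighbouring tissues, were tested with camera of limma at its preset correlation of 0.01, with p-values adjusted over the lists within a contrast. Camera with a correlation estimated for each list was run beside it. So was fry, which asks whether the genes of a list move on balance in 1 direction. Splits of the same mice in other ways, given below, called a median of 7 to 9 lists at the preset correlation. A list called at that correlation alone is therefore weak evidence. Some lists share members, Aqp2 being in several, so their results are not independent of each other. The groups, contrasts, gene lists, tests, the alternatives that the closing part does not mark as added later, and the rule for named genes were chosen before the data were examined. The rule took, for each contrast, the 10 largest rises and the 10 largest falls among called genes with a mean value of at least 50, without unnamed gene models, then up to 4 members of each list with the smallest p in the mean contrast, and always Aqp2, Aqp3, Avpr2, Slc14a2, Nfat5, Slc5a3, Slc6a12, Akr1b3, Sgk1, Fkbp5, Per1, Ren1, Xist and Ddx3y. Where these were too many, the first of each rank are named. Grem1, Mcoln3, Tmem204, Cry1, Frzb, Cyp2c44 and the unnamed gene ENSMUSG00000119584 were chosen after their values were seen. Avpr2 lay below the filter. Some genes that the rule takes are not reported here, though they enter the counts.

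The model was tested on simulated counts drawn for the same 17592 genes, with known changes in genes with a mean value of at least 50. Each gene was drawn independently, with 1 dispersion for all libraries. The simulation thus held no correlation between genes and no libraries that stand apart, so its rates may not carry over to the real data. In the female contrast 74.6% of genes changed by 1.5-fold and 97% of those changed by 2-fold were recovered, in the male contrast 86.6% and 97%, and in the difference between the responses 49.3% and 89.6%. False calls made up 4.74% of the calls in the female, 4.08% in the male and 5.36% in the difference contrast.

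The alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, scaling by the TMM factors of edgeR 4.0.16, quantile normalization, the quasi-likelihood test of edgeR and the Wald test of DESeq2 1.42.0 on the recovered reads, a prior variance without the robust option, weights per library, each sex fitted alone, the replicate number as a block, the balance of cortex to medulla markers as a covariate, deprived female 5 counted as watered, stricter thresholds, and each library left out in turn. The balance called that of cortex to medulla was the mean of proximal tubule markers less that of thick ascending limb and intercalated cell markers. It used no list of inner medulla markers, so it is only a partial measure of how much medulla a piece held. After the data were seen, 4 libraries that stood apart from the rest of their groups were left out, alone and with edgeR. Also after the data were seen, the log2 value of the unnamed gene was entered as a covariate. Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and weights and estimated correlations used statmod 1.5.0. No 2 libraries of a group agreed within sampling noise, the chi-square per degree of freedom of pairs ranging from 3.33 to 138.34.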

Results

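Gene expression was measured in kidney tissue from 24 mice, to compare mice kept 9 to 11 h without water with watered mice of each sex. The groups held 6 watered females, 5 water-deprived females, 6 watered males and 7 water-deprived males, each library coming from 1 mouse. Libraries held 14411843 to 29398960 reads assigned to the genes of the table, the females from 15017319 and the males up to 25348398. Values are the authors' size-factor normalized counts. In 4 libraries the unnamed gene ENSMUSG00000119584 took 1.074% to 2.858% of reads, against 0.268% to 0.85% in the other 20. These were watered female 6 (1.905%), deprived female 1 (1.074%) and deprived males 6 (1.287%) and 7 (2.858%). The first component of the variation within sexes held 42.5% of that variance. The treatment label of deprived female 5 disagreed with its title, and its values of Aqp2 (12719) and Aqp3 (3196) lay above those of all 6 watered females.

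In females, the kidney raised its water channels and osmolyte transporters and lowered several clock genes. Aqp2, the vasopressin-regulated water channel of the collecting duct (chromosome 15, 99579055 to 99584547), rose from 8697 ± 1661 (SD, n = 6) to 14341 ± 1392 (SD, n = 5), a log2 change of 0.74 ± 0.12 (SE, limma adjusted p = 0.004). Nr1d1, the REV-ERB alpha repressor of the clock (chromosome 11, 98767932 to 98775333), went from 326.2 ± 21.1 to 148.0 ± 19.9, a change of -1.14 ± 0.15 (limma adjusted p = 0.0006). Of 17592 genes tested, 139 changed, 79 higher and 60 lower, with a median absolute log2 change of 0.49.

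Further rises in females were those of Gem, a small GTPase that restrains calcium channels, by 1.44 ± 0.26, and Slco4a1, an organic anion transporter, by 1.06 ± 0.22 (limma adjusted p = 0.0079 and 0.018). Bcat1, a branched-chain aminotransferase, rose by 0.95, Spag5, a mitotic spindle protein, by 0.93, and Tmem45a, a membrane protein, by 0.92. Pappa, a protease of insulin-like growth factor binding proteins, rose by 0.88, Htr1b, a serotonin receptor, by 0.85, and Itih2, a hyaluronan-binding inter-alpha-inhibitor chain, by 0.79. Among the falls, Slc25a25, a mitochondrial ATP-Mg carrier, changed by -1.04 ± 0.19 and Id1, a bone morphogenetic protein target that blocks helix-loop-helix factors, by -0.92 ± 0.20 (limma adjusted p = 0.0079 and 0.023). Its relative Id4 changed by -0.64, Dbp, a clock output factor, by -0.79, Slc38a3, a glutamine transporter, by -0.74, and Tmem14a by -0.63. The P450 genes Cyp4a12a and Cyp2d9 changed by -0.74 and -0.62, and both are uncertain because close paralogs can share their reads. Slc13a2os, antisense to the citrate transporter gene Slc13a2, changed by -1.04. Its reads cannot be told from those of its partner, since the use of strand in counting is not known.

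The list of tonicity and organic osmolyte genes rose in females, with 4 of 12 measured members higher, or 7 adjusted over the list alone, and none lower. The 4 were Aqp2, the betaine transporter Slc6a12 (0.79 ± 0.14, from 93.3 ± 12.9 to 161.7 ± 20), the myo-inositol transporter Slc5a3 (0.41 ± 0.09) and the neutral amino acid transporter Slc38a2 (0.60 ± 0.13). The list's median log2 change was 0.37 (camera of limma, adjusted p = 3.4e-10, and adjusted p = 0.026 with an estimated correlation). Aldose reductase Akr1b3, the sorbitol-making enzyme, had 1.10 ± 0.32 (limma adjusted p = 0.13), while Nfat5, the factor that drives such genes, had -0.01 ± 0.12 and the urea transporter Slc14a2 0.10 ± 0.11 (limma adjusted p = 0.99 and 0.9). Nfat5 was at 1873.8 in deprived female 1, 1 of the 4 libraries named above, against 2840.4 to 3045.4 in the other deprived females. That library thus lowers the Nfat5 change. In the collecting duct transport list 2 of 11 measured members rose, Aqp2 and the basolateral channel Aqp3 (0.42 ± 0.07), and 1 fell, the glucocorticoid-inactivating enzyme Hsd11b2 (-0.28 ± 0.07). Adjusted over the list alone 3 were higher and 2 lower, and its median of -0.11 had the opposite sign to its mean of 0.03 (camera of limma, adjusted p = 0.71). In the clock list 1 of 21 members rose, Cry1 (0.37 ± 0.09), and 4 fell, Nr1d1, Dbp, Nr1d2 (-0.60 ± 0.09) and Per3 (-0.58 ± 0.12). Adjusted over the list alone 4 were higher and 7 lower (camera of limma, adjusted p = 0.17).

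Markers of stroma and smooth muscle were higher in deprived females, with 2 of 9 measured members risen, the collagens Col3a1 (0.65 ± 0.13) and Col1a2 (0.49 ± 0.10). The count was 4 adjusted over the list alone (camera of limma, adjusted p = 3e-06, and adjusted p = 0.057 with an estimated correlation). Of 9 endothelial markers 0 passed over all genes and 5 were higher adjusted over the list alone. The list median was 0.21 (camera of limma, adjusted p = 1.4e-07, and adjusted p = 0.057 with an estimated correlation). Proximal tubule markers were lower, with 2 of 14 fallen, among them the organic anion transporter Slc22a6 (-0.46 ± 0.09). The count adjusted over the list alone was 4 (camera of limma, adjusted p = 8.3e-05, and adjusted p = 0.09 with an estimated correlation). The female count of 139 was 741 without the 4 libraries named above, 135 genes being in both, 364 with DESeq2, 1003 with weights per library, 74 with the balance of cortex to medulla markers as a covariate and 2 with deprived female 5 counted as watered; leaving out watered females 2 or 5, deprived females 3, 4 or 5, or deprived male 7 gave 66, 86, 81, 70, 68 and 215. Of the 41 female calls among the genes named, 19 missed the threshold in some fit that left out 1 library, with a limma adjusted p of at most 0.16 (0.061 for Itih2 without deprived female 5 and 0.057 for Per3 without deprived female 4). Of the 24 such fits Cry1 passed in 6, Frzb in 7, Hsd11b2 in 9, Cyp4a12a in 10 and Pappa in 15, and the other 14 in 16 to 23. Without the 4 libraries the female calls of Bcat1 and Cyp4a12a were lost (limma adjusted p = 0.05 and 0.12), at changes of 0.92 and -0.68.

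**Figure D1:**
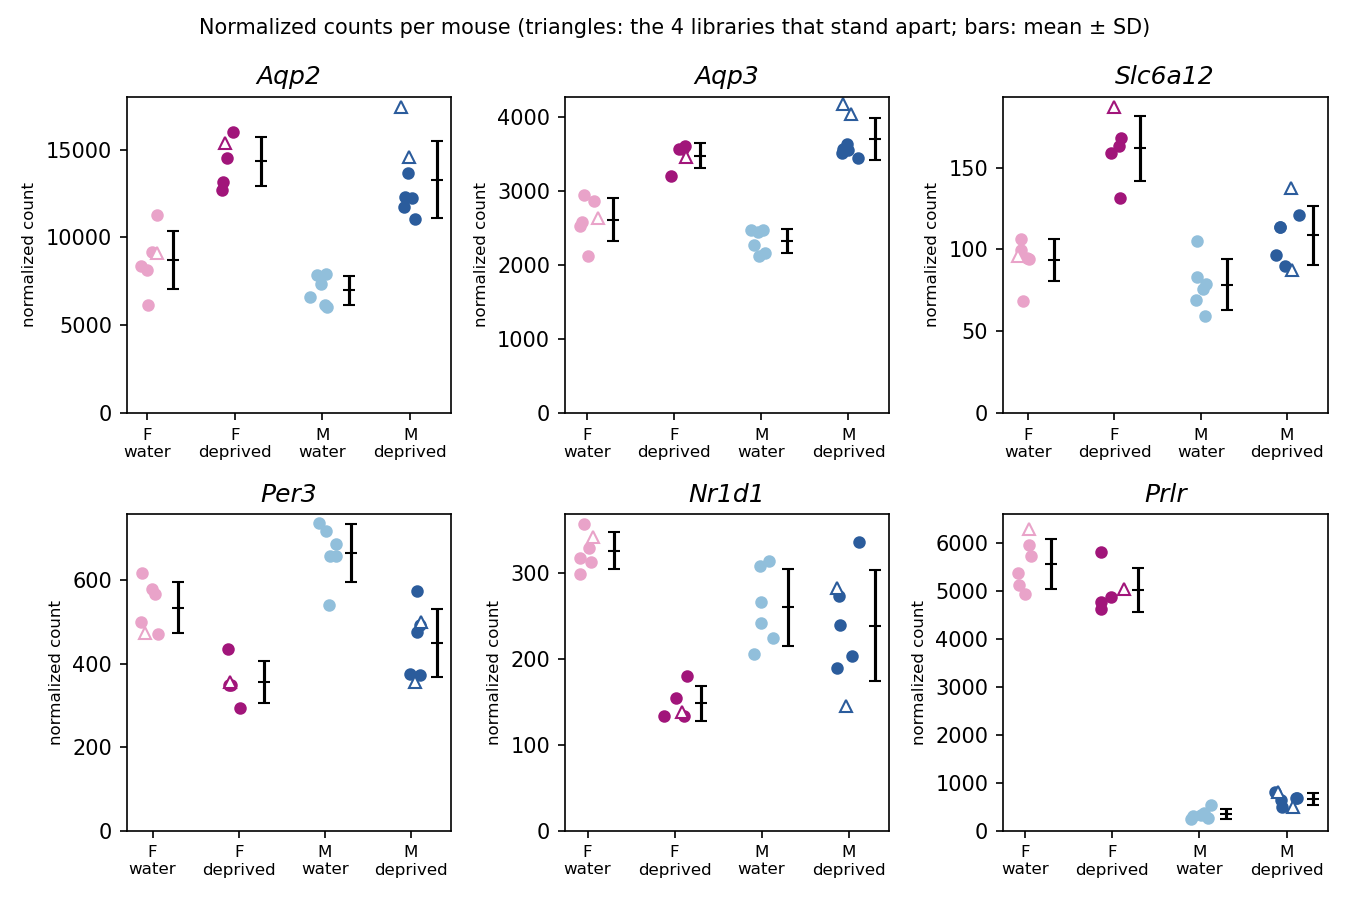
Normalized counts (linear axes from 0) of Aqp2, Aqp3, Slc6a12, Per3, Nr1d1 and Prlr in each mouse, by sex and water group, with black bars for the mean and SD and open triangles for the 4 libraries with 1.074% to 2.858% of reads on the unnamed gene ENSMUSG00000119584. Aqp2 went from a mean of 8697 to 14341 in females and from 6983 to 13291 in males, whereas Nr1d1 had means of 326.2 and 148.0 in females and 259.9 and 238.5 in males.

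In males, the same question gave a rise of the water channels and of the prolactin receptor Prlr, and a fall of the clock gene Per3. Aqp2 rose from 6983 ± 841 (SD, n = 6) to 13291 ± 2181 (SD, n = 7), a log2 change of 0.92 ± 0.11 (SE), and Aqp3 (chromosome 4, 41092722 to 41098183) from 2322 ± 160.4 to 3702 ± 285.3, by 0.67 ± 0.07 (limma adjusted p = 5.2e-05 and 2e-06). Prlr (chromosome 15, 10177238 to 10349180) rose from 337.2 ± 106.5 to 654.9 ± 127.0, by 0.98 ± 0.14 (limma adjusted p = 0.001).

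Other rises in males were those of Pappa, by 1.17 ± 0.19, the cytokinesis motor Kif23, by 0.90 ± 0.16, and the nuclear matrix protein gene Banp, by 0.73 ± 0.13 (limma adjusted p = 0.0023, 0.0061 and 0.01). Ddit4l, an inhibitor of mTOR signalling, rose by 0.71, the sialyltransferase St6galnac3 by 0.69 and the stress-induced Fam129a by 0.69. Among the falls, Mfsd2a, a lysophospholipid transporter, changed by -0.95 ± 0.18, Wdr86 by -0.71 ± 0.14 and the clock gene Per3 by -0.58 ± 0.11 (limma adjusted p = 0.015, 0.015 and 0.012). The zinc finger factor Ovol1 changed by -0.57, the paraspeckle RNA Neat1 by -0.52, the sterol sensor partner Insig1 by -0.45 and the sialyltransferase St6gal1 by -0.40. The ammonia transporter Rhbg of the collecting duct changed by -0.37 and the clock repressor Cry2 by -0.40. In all, 40 genes changed, 25 higher and 15 lower, with a median absolute log2 change of 0.67.

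Of the tonicity and osmolyte list 1 of 12 members rose in males, Aqp2, or 4 adjusted over the list alone, with a list median of 0.18 (camera of limma, adjusted p = 0.012, and adjusted p = 0.49 with an estimated correlation). Slc6a12 had 0.47 ± 0.13, Slc5a3 0.34 ± 0.08 and Akr1b3 0.39 ± 0.30 (limma adjusted p = 0.13, 0.074 and 0.57). In the clock list 1 of 21 members rose, Nfil3, a repressor of clock output (0.56 ± 0.12), and 2 fell, Per3 and Cry2. This was 1 and 5 adjusted over the list alone (camera of limma, adjusted p = 0.22). Cholesterol synthesis genes were lower as a list, with 1 of 19 fallen, Insig1. The count adjusted over the list alone was 4 (camera of limma, adjusted p = 4e-06, and adjusted p = 0.47 with an estimated correlation). The list of principal cell markers was called higher through Aqp2 and Aqp3, 2 of its 8 members, or 2 adjusted over the list alone. Its median of -0.02 had the opposite sign to its mean of 0.19 (camera of limma, adjusted p = 0.033, and adjusted p = 0.47 with an estimated correlation). The genes of cytosolic ribosomal proteins and of the nuclear-encoded respiratory chain had list medians of 0.17 and 0.15 (camera of limma, adjusted p = 8.2e-07 and 4e-06, and adjusted p = 0.82 for both with an estimated correlation). Of their 81 and 78 members 0 passed, or 0 adjusted over the list alone, and the medians were -0.04 and -0.05 without the 4 libraries, which include 2 of the 7 deprived males.

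The male count of 40 was 142 without the 4 libraries, 36 genes being in both, 157 with DESeq2, 133 with weights per library and 11 with males fitted alone. Leaving out watered males 3 or 4 or deprived male 3 gave 22, 25 and 65 genes, and 9 of the 23 male calls among the genes named missed the threshold in some such fit (limma adjusted p = 0.12 at most, 0.057 for Mfsd2a without watered male 3 and 0.052 for Wdr86 without watered male 4). Of the 24 fits St6gal1 passed in 5, Cry2 and Fam129a in 6 and Nfil3 in 11, and the other 5 in 18 to 23. Without the 4 libraries the male calls of Mfsd2a and Nfil3 were lost (limma adjusted p = 0.061 and 0.092), at changes of -0.97 and 0.58. Of the 18 other alternatives these calls held in 14 and 11.

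Averaged over both sexes, 289 genes changed with water deprivation, 168 higher and 121 lower, with a median absolute log2 change of 0.30. Aqp3 rose by 0.55 ± 0.05 and Aqp2 by 0.83 ± 0.08 (limma adjusted p = 2.7e-07 and 1.1e-06). Per3 fell by 0.58 (SE 0.08) and Nr1d2 by 0.47 (SE 0.06) on the log2 scale (limma adjusted p = 0.00015 and 0.00012). Gem rose by 1.14, Pappa by 1.03, Kif23 by 0.82, Slco4a1 by 0.80, Htr1b by 0.73, Spag5 by 0.72 and Ddit4l by 0.70, and Rasd1, a dexamethasone-induced small G protein, by 0.72. The sodium-activated potassium channel gene Kcnt1 changed by -0.75, the secreted signal Wnt9b by -0.73, Slc13a2os by -0.73, Slc25a25 by -0.71, Nr1d1 by -0.65, Dbp by -0.58, Ovol1 by -0.54, the glycosyltransferase Extl1 by -0.50 and Cyp4a12a by -0.47.

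The tonicity list rose on average, with 4 of 12 members higher, Aqp2, Slc6a12 (0.63 ± 0.10), Slc38a2 (0.45 ± 0.08) and Slc5a3 (0.38 ± 0.06). Adjusted over the list alone 6 were higher (camera of limma, adjusted p = 4e-08, and adjusted p = 0.082 with an estimated correlation). Of 20 corticosteroid response genes 5 rose, or 7 adjusted over the list alone. Among the 5 were the kinase Sgk1 (0.64 ± 0.13), the leucine zipper gene Tsc22d3 (0.35 ± 0.08) and the cell cycle inhibitor Cdkn1a (0.66 ± 0.16), and the list median was 0.22 (camera of limma, adjusted p = 4.2e-07, and adjusted p = 0.24 with an estimated correlation). In the same list Fkbp5, a classical glucocorticoid target, had -0.01 ± 0.18 and Per1 0.29 ± 0.12 (limma adjusted p = 0.99 and 0.29). In the clock list 2 members rose, among them Nfil3 (0.54 ± 0.09), and 5 fell, or 4 and 7 adjusted over the list alone (camera of limma, adjusted p = 0.08). Cholesterol synthesis genes were lower, with 3 of 19 fallen, Insig1 (-0.37 ± 0.06), Srebf2, the master regulator (-0.21 ± 0.05), and Msmo1, a sterol oxidase (-0.27 ± 0.07). With p-values adjusted over the list alone 10 were lower (camera of limma, adjusted p = 4e-08, and adjusted p = 0.14 with an estimated correlation). Of 11 collecting duct transport genes Aqp2 and Aqp3 rose and Hsd11b2 (-0.18 ± 0.05) and the sodium channel subunit Scnn1b (-0.18 ± 0.04) fell. Adjusted over the list alone these were 2 and 3, and the list's median of -0.13 had the opposite sign to its mean of 0.04 (camera of limma, adjusted p = 0.77). The vasopressin receptor Avpr2 lay near the floor, at 6.65 ± 3.14 and 6.25 ± 1.32 in watered and deprived females (SD, n = 6 and 5). In males it was at 5.77 ± 4.68 and 3.32 ± 2.20 (SD, n = 6 and 7), and no difference was detectable at this depth. Of 9 endothelial markers 3 rose, Plvap (0.21 ± 0.04), Tie1 (0.17 ± 0.04) and Pecam1 (0.18 ± 0.05). In all, 5 were higher adjusted over the list alone (camera of limma, adjusted p = 6.3e-06, and adjusted p = 0.16 with an estimated correlation).

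The count of 289 was 1230 without the 4 libraries, 275 genes being in both, 562 with DESeq2, 1165 with weights per library, 527 with the unnamed gene as a covariate and 120 with deprived female 5 counted as watered. Leaving out watered female 2, deprived female 4 or watered male 1 gave 169, 179 and 189 genes, and 15 of the 51 calls among the genes named missed the threshold in some such fit, the limma adjusted p reaching 0.1 at most. Of the 24 fits Mthfd2 passed in 5, Hsd11b2 and Prlr in 6, Cyp4a12a, Pecam1 and Rasd1 in 7, Msmo1 in 8 and Klf4 in 9, and the other 7 in 13 to 19. Without the 4 libraries the average calls of Cdkn1a, Rasd1 and Cyp4a12a were lost (limma adjusted p = 0.059, 0.094 and 0.11), at changes of 0.59, 0.63 and -0.44.

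To ask whether the sexes respond alike, both responses were set side by side. Grem1, a secreted antagonist of bone morphogenetic proteins, rose by 2.47 ± 0.41 in females and 3.22 ± 0.38 in males (SE, limma adjusted p = 0.004 and 3.6e-05). Its level was low, going from 4.78 to 29 in females and from 4.34 to 42 in males. In all 9 genes rose in both sexes, among them Pappa, Aqp2, Kif23, Ddit4l, the lysosomal channel gene Mcoln3 (0.61 and 0.64), Aqp3 and the endothelial membrane protein gene Tmem204 (0.40 and 0.43), and Ovol1 and Per3 fell in both. Independent lists would share 0.112 rises and 0.0512 falls. The single fit shares 1 estimate of the spread per gene between the sexes, which can raise the overlap above these. The 11 genes were 51 without the 4 libraries, 36 with DESeq2, 7 with each sex fitted alone, 17 without deprived female 1 and 17 without deprived male 7. With deprived female 5 counted as watered limma gave 0, having called 2 genes in females. Of the 139 genes called in females 110 had the same sign in males (79.1%), and of the 40 called in males 32 had the same sign in females. The share over all genes was not counted. Changes were smaller in the other sex. The median was 0.49 in females for genes called there and 0.14 in males, counted in the female direction. For genes called in males it was 0.67 in males and 0.30 in females, counted in the male direction. Choosing genes by their call in 1 sex favours larger changes in that sex. Across all 17592 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.13 and a Spearman rho of 0.11, with a jackknife SE of 0.19 for r over libraries. That r was 0 without deprived female 1, 0.23 without watered female 6 and 0.21 without the 4 libraries.

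**Figure D2:**
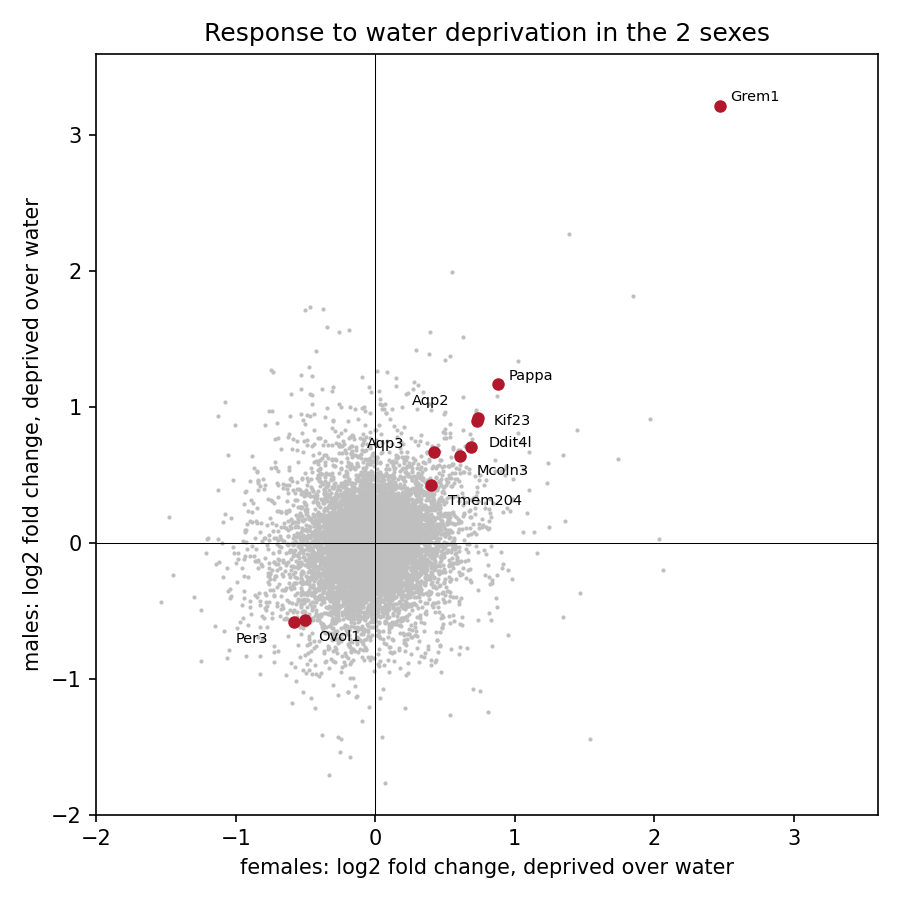
Log2 change with water deprivation in females (x axis) and males (y axis) for 17592 genes (grey points), with the genes named in the text and called in both sexes in red and labelled. The rises lie in the upper right and the 2 falls, Ovol1 and Per3, in the lower left, while the grey points show a Pearson r of 0.13.

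The difference between the responses passed for 0 genes with limma, whose smallest adjusted p was 0.077, while 1248 genes had an unadjusted p under 0.05. DESeq2 gave 46 genes, edgeR 0, weights per library 9 and the unnamed gene as a covariate 4. Limma without the 4 libraries gave 9, among them Nr1d1, Id4, the epoxygenase gene Cyp2c44 and the Wnt antagonist gene Frzb. Leaving out watered male 1 or deprived males 6 or 7 gave 2, 1 and 3 genes. Prlr was 1.13 ± 0.21 higher in the male than in the female response, with -0.15 ± 0.15 in females, and Nr1d1 0.99 ± 0.21 higher, with -0.15 ± 0.14 in males (limma adjusted p = 0.077 and 0.13). Frzb differed by -0.64 ± 0.12 and Cyp2c44 by 0.49 ± 0.09 (limma adjusted p = 0.077 for both), and Bcat1 by -1.16 ± 0.28 (limma adjusted p = 0.23). Among the fixed lists, the genes of the unfolded protein response differed by a median of -0.33, with 11 of 15 lower in males adjusted over the list alone and 0 over all genes (camera of limma, adjusted p = 2.4e-11, and adjusted p = 0.1 with an estimated correlation). Hyou1, a chaperone of the endoplasmic reticulum, had 0.18 ± 0.10 in females and -0.38 ± 0.09 in males, and the disulfide isomerase Pdia6 0.30 ± 0.09 and -0.18 ± 0.08.

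With water, sex was a far larger source of variation than water deprivation, with 5361 genes different between males and females, 2803 higher and 2558 lower in males, 800 of them by over 2-fold. The Y-linked Ddx3y, an RNA helicase gene, was at 1194 ± 46.7 in males and 2.43 ± 1.02 in females (SD, n = 6 and 6), and Xist, the RNA that silences an X chromosome, at 31.4 ± 13.8 and 10441 ± 1418, log2 differences of 8.49 ± 0.21 and -8.44 ± 0.22 (SE, limma adjusted p = 3.9e-21 and 2.5e-20). The Y genes Uty, Eif2s3y and Kdm5d were higher in males by 8.09, 7.99 and 7.85, and share sequence with X-linked copies. The organic anion transporter Slco1a1 (8441 ± 1539 against 19.9 ± 4.96) and the amino acid transporter Slc7a13 (24704 ± 2104 against 93.2 ± 23) of the proximal tubule were higher in males by 8.67 and 8.07. The protease inhibitor Pzp was higher in males by 7.18 and the acyl-CoA synthetase Acsm3 by 6.97. With close paralogs that make them uncertain, the P450 Cyp2j13 was higher by 7.90 and the glucuronosyltransferase Ugt2b37 by 6.51. Higher in females were Ugt1a2, which shares exons with other Ugt1a genes (a difference of -8.0), the phosphate transporter family member Slc17a2 (-6.11), the skeletal myosin Myh1 (-6.0) and the amino acid transporter Slc7a12 (-5.85). So were the efflux pump Abcc3 (-5.43), the serine protease Tmprss6 (-5.17), the fatty acid hydroxylase Cyp4a14 (-4.72, with close paralogs), the growth factor Igf2 (-4.46) and Prlr (-4.09 ± 0.15). All 23 of the sex differences named passed in each fit that left out 1 library, with a limma adjusted p of at most 0.023.

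The 9 measured androgen-associated proximal tubule genes were all higher in males, or 9 adjusted over the list alone (camera of limma, adjusted p = 1.6e-22, and adjusted p = 7.8e-05 with an estimated correlation). Of 7 female-associated ones 5 were lower and 1 higher in males, or 6 and 1 adjusted over the list alone (camera of limma, adjusted p = 3.1e-06, and adjusted p = 0.018 with an estimated correlation). The Y-linked genes and Xist, a list of 5, had 4 higher and 1 lower in males, or 4 and 1 adjusted over the list alone (camera of limma, adjusted p = 5.6e-05, and adjusted p = 0.02 with an estimated correlation). Heat shock genes were higher in males, 14 of 19, or 16 adjusted over the list alone (camera of limma, adjusted p = 2e-10, and adjusted p = 0.02 with an estimated correlation). Dnaja1, a co-chaperone, was higher by 1.06 ± 0.06, while the small heat shock protein Cryab had 0.16 ± 0.20 (limma adjusted p = 0.59). All 7 podocyte markers were lower in males, or 7 adjusted over the list alone (camera of limma, adjusted p = 0.00025, and adjusted p = 0.1 with an estimated correlation). Among them were the transcription factor Wt1 (-0.73 ± 0.11) and the surface sialomucin Podxl (-0.33 ± 0.10), the latter at 0.15 with the balance of cortex to medulla markers as a covariate. Markers of some other parts of the nephron were lower in males too. Their medians were -0.327 for intercalated cells, -0.276 for the thick ascending limb and -0.285 for principal cells against -0.487 for podocytes. In these lists 5 of 10, 5 of 8 and 4 of 8 were lower and 0 higher, or 7, 7 and 5 adjusted over the list alone (camera of limma, adjusted p = 0.0028, 0.0059 and 0.022, and adjusted p = 0.15, 0.24 and 0.18 with an estimated correlation). With that covariate, built from markers that include those of the thick ascending limb and intercalated cells, the medians in the same order were 0.029, -0.011, -0.4 and -0.102 (camera of limma, adjusted p = 0.92, 0.92, 0.2 and 0.45). Without the covariate 5 of 14 proximal tubule markers were higher and 3 lower in males, or 5 and 3 adjusted over the list alone. Of 7 distal convoluted tubule markers 1 was lower, or 1 adjusted over the list alone. Neither list was called (camera of limma, adjusted p = 0.28 and 0.27). Cholesterol synthesis genes were higher in males in 13 of 19 cases and lower in 1, or 13 and 1 adjusted over the list alone. The list median was 0.46 (camera of limma, adjusted p = 1.8e-06, and adjusted p = 0.1 with an estimated correlation). That covariate is tied to sex. Its lists had mean log2 differences between watered males and females of 0.194 (proximal tubule), -0.285 (thick ascending limb) and -0.338 (intercalated cells). With the covariate 1005 genes differed between the sexes, 863 of them among the 5361. Neither this drop nor the medians given with the covariate can separate tissue make-up from sex. Without the 4 libraries 7395 genes were called.

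Between deprived males and deprived females 5830 genes differed, 3082 higher and 2748 lower in males, 745 of them by over 2-fold. The transporter Slco1a1 stood at 6688 ± 743 in deprived males and 24.4 ± 13 in deprived females (SD, n = 7 and 5), Slc7a13 at 24425 ± 857 and 88.7 ± 22.9, and Prlr at 654.9 ± 127.0 and 5017 ± 462. Ugt1a2 was at 40.7 ± 23.1 in deprived males and 11058 ± 1590 in deprived females, and Abcc3 at 65.8 ± 9.95 and 2701 ± 526. The count was 7184 without the 4 libraries and 332 with the covariate, 312 of these among the 5830. Since the covariate is tied to sex, this drop too cannot separate tissue make-up from sex.

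**Figure D3:**
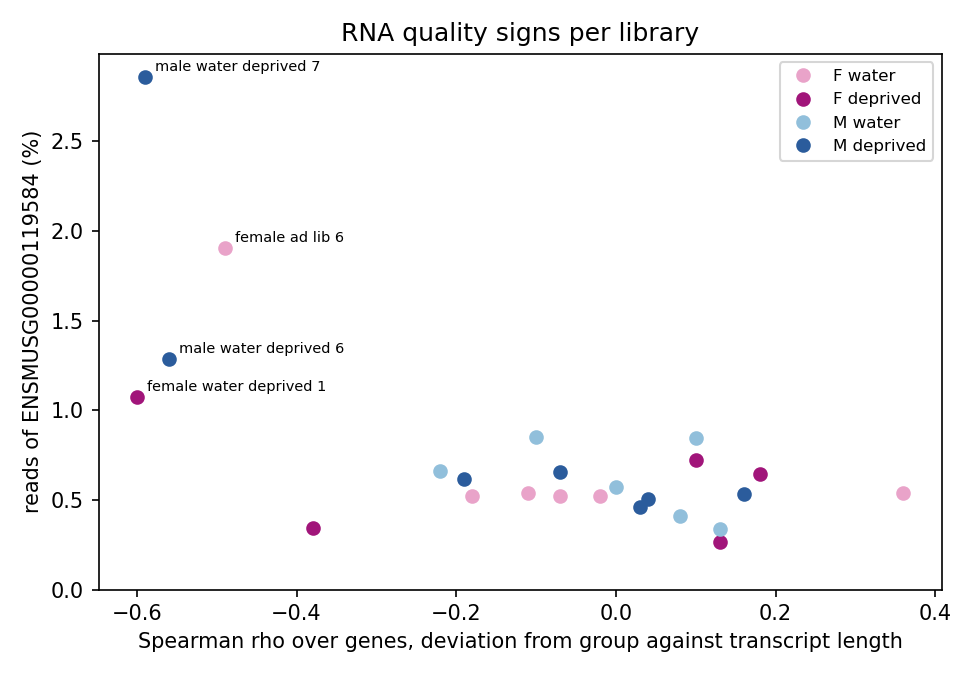
Percent of reads on the unnamed gene ENSMUSG00000119584 (y axis, from 0) against the Spearman correlation, across genes within a library, of the deviation from its group with transcript length (x axis), 1 point per library coloured by group. The 4 libraries at 1.074% to 2.858% of reads lie at correlations of -0.60 to -0.49, and the other 20 at -0.38 to 0.36.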

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

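Of the tests here, those of another cell type, of GC content and of a later collection time were written before their results were seen; those of transcript length, of a cell type shared by the 4 libraries, of the clock genes and the water channels without them, of collecting duct share and of scaling, and the splits of the samples, were chosen only after the results they bear on had been seen.

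Watered female 6, deprived female 1 and deprived males 6 and 7, which fall in 3 of the 4 groups, stood apart from their groups, and no biological explanation was tested. They had interquartile ranges of the genes' deviations of 0.37 to 0.77 against 0.20 to 0.29 in the other 20, and a loss of long transcripts, as from lower RNA quality, may account for this, since the deviations fell with transcript length with a Spearman rho across genes of -0.60 to -0.49, the highest being -0.49, against -0.38 to 0.36 elsewhere. The tables argue against GC content, whose partial rho at fixed length was at most 0.24 in size, while that of length at fixed GC content was -0.63 to -0.49. Another cell type in the piece cannot be told apart: its bound, set beforehand, was passed at 3.75 times the interquartile range by adipocyte markers that were 1.39 lower in watered female 6, but all of the other 20 libraries pass that bound too, so this reading of it was set afterwards. Above the highest of the other 20 lay leukocyte markers (0.82 and 1.05 against 0.39) and principal cell markers (0.22 and 0.35 against 0.18) in deprived males 6 and 7, erythrocyte markers in deprived male 6 (0.78 against 0.61) and urothelial ones in deprived male 7 (0.77 against 0.52), while 0 of 12 lists did so in all 4 libraries and distal convoluted tubule markers lay below the other 20 in all 4 (-0.48 to -0.32 against -0.19 at lowest).

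Clock genes differed between water groups, 2 of 21 being higher and 5 lower on average, though the list as a whole was not called (camera of limma, adjusted p = 0.08). Leaving out the 4 libraries argues against them as the cause, the mean change of the 5 lower genes then being -0.51. Collection at a later time within the stated window, whose hours do not fully match the stated time of water removal, cannot be told apart from an effect of water deprivation: the score of these 7 genes (mean log2 value of the 2 less that of the 5) shifted by 1.65 times its range among watered females and 0.87 times that among watered males, but its genes were picked for their change between these groups, so these ratios decide nothing. Clock times of the single mice were not used here. A phase difference tied to water deprivation may be present and remains a hypothesis.

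Aqp2 and Aqp3 were higher in deprived mice of both sexes, on average by 0.83 and 0.55. A larger share of collecting duct as a whole would raise the other 6 principal cell markers too, but their median change was -0.09 (SD 0.16, from -0.18 to 0.22). The 6 were not split by kidney zone. Their median therefore cannot decide whether the deprived pieces held more medulla and less cortex, which remains open. The choice of scaling made little difference, the change of Aqp2 being at least 0.83 under TMM and quantile scaling. These scalings barely move the genes as a whole, whose median average change was -0.011 and -0.001 against -0.007. They are therefore a weak test of scaling. Deprived males 6 and 7 had the highest male values of both genes. Principal cell markers lay high in them too, but that list includes Aqp2 and Aqp3 themselves. Without the 4 libraries the average changes of Aqp2 and Aqp3 were 0.77 and 0.52 (limma adjusted p = 9.6e-05 and 8.6e-08). A response of the RNA of these channels to water deprivation may underlie this, a hypothesis found and tested on the same data.

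Splitting the same mice in other ways asks whether a total count of calls could come from chance, with 1 of 100 as the lowest share possible. It does not bear on single genes, nor on other differences between the groups such as collection time, tissue make-up or RNA quality. Among 100 splits, the real one included, 1 gave as many genes as the 139 in females (highest other 0), 1 as many as the 40 in males (highest other 6), and 1 as many as the 289 on average (highest other 2). The same held, with 1 of 100, for the 11 genes of both sexes (highest other 0), the 5361 genes between the sexes with water (highest other 3) and the 5830 between deprived mice (highest other 1978). For the difference between the responses 100 of 100 splits gave at least 0 genes (highest other 1), which excludes nothing, and with 20 libraries 2 of 100 gave at least the 9 found (highest other 11). For the number of lists called, chance was not excluded in females (15 lists, 13 of 100 splits, highest other 23), on average (15 lists, 5 of 100, highest other 16), for the difference (13 lists, 10 of 100, highest other 18) or between the sexes (15 lists, 15 of 100, highest other 21), whereas in males 2 of 100 gave at least 13 (highest other 13). With 20 libraries, however, 14 of 100 splits in males gave at least the 11 lists found (highest other 14), so that chance was not excluded there. With all 24 libraries, the other splits called a median of 9 lists in females, 7 in males and 8 on average. They called a median of 8 for the difference and 9 between the sexes. The preset correlation thus calls many lists in mice split at random, and its adjusted p-values overstate the evidence for a list. For the Pearson r of 0.13 between the responses 15 of 100 splits were as high (highest other 0.32), and for the 0.21 of 20 libraries 1 of 100.

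Single mice lay far from the rest of their group by a gap test in 37 of 408 tests, where chance gives about 1 in 20, or 20.4, and 18 of the 37 were in the 4 libraries. Watered female 1 had Slc6a12 at 68.7 (others 94.4 to 106.4) and Kif23 at 94.8 (137.3 to 157.6). Watered female 2 had Slc22a6 at 9926.3 (8266.0 to 8738.5), and watered female 3 had St6galnac3 at 49 (66.7 to 75.4). Watered female 6 had Ugt1a2 at 9979.7 (11939.7 to 12944.7), Podxl at 4631.2 (5469.5 to 5740.9) and 1.9% of reads on the unnamed gene (0.521 to 0.541). Deprived female 1 had Pappa at 284.3 (616.9 to 676.7), Id4 at 1382.0 (882.7 to 977.3), Nfat5 at 1873.8 (2840.4 to 3045.4) and Podxl at 4494.4 (5645.1 to 6054.2). Deprived female 5 had Abcc3 at 3630.1 (2350.3 to 2558.3).

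Watered male 5 had Slc22a6 at 15312.2 (20353.9 to 22882.0), Col3a1 at 1071.8 (664.4 to 809.6) and Col1a2 at 1882.1 (1343.2 to 1482.7). The same mouse had Tie1 at 1091.1 (913.5 to 959.3), Cyp2j13 at 4459.2 (7099.6 to 8547.3) and Cyp4a14 at 2466.8 (248.8 to 681.0). Watered male 1 had Banp at 353.9 (197.4 to 252.5) and watered male 2 had Kif23 at 59 (92.4 to 107.5). Watered male 4 had Wdr86 at 108.1 (65.9 to 80) and Acsm3 at 20553.0 (16469.9 to 17969.9). Watered male 6 had St6galnac3 at 44.2 (31.2 to 35.9), Nfil3 at 448.2 (256.4 to 328.0) and Cdkn1a at 240.1 (124.6 to 164.1).

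Deprived male 3 had Itih2 at 206.9 (262.6 to 304.9). Deprived male 6 had Dnaja1 at 7993.4 (9374.0 to 10263.2) and 10.4% of reads on mitochondrially encoded proteins (7.92 to 8.36). Deprived male 7 had Slc25a25 at 3301.7 (1322.0 to 1955.3), Id1 at 680.3 (252.8 to 357.1), Slc38a3 at 2070.6 (1001.2 to 1288.9) and Ddit4l at 517.6 (349.4 to 419.5). It also had Klf2 at 889.8 (412.7 to 520.6), Nqo1 at 1633.1 (896.9 to 1119.1), Cyp4a14 at 4287.7 (360.5 to 852.4), Cryab at 5842.9 (1649.5 to 3206.8) and 2.86% of reads on the unnamed gene (0.461 to 1.29).

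The response differed between the sexes for 13 lists by camera of limma at its preset correlation, and for 0 with an estimated one. Medians of the male minus the female log2 change were -0.176 for tonicity and osmolyte genes, -0.223 for heat shock, -0.329 for the unfolded protein response and -0.295 for the cell cycle. They were 0.285 for fatty acid oxidation, 0.177 for the NRF2 response, 0.197 for ribosomal proteins, 0.179 for the nuclear-encoded and 0.239 for the mitochondrially encoded respiratory chain. For markers they were 0.102 for proximal tubule, -0.136 for endothelium and -0.228 for stroma and smooth muscle, and for the female-associated proximal tubule genes 0.173. The calls of ribosomal proteins and of the nuclear-encoded respiratory chain were lost without the 4 libraries (0.014 and -0.003), with the unnamed gene (0.001 and -0.005) or the cortex to medulla balance (0.065 and 0.037) as a covariate, and without deprived male 7 alone (0.055 and 0.049), the adjusted p by camera of limma being 0.077 to 0.91. Mitochondrially encoded proteins lost theirs without deprived female 4 (0.087) and with quantile normalization (0.198), proximal tubule without deprived female 1 (0.11) and with quantile normalization (0.01), and endothelium without watered male 5 (-0.099) and with the cortex to medulla covariate (-0.058). The tonicity list lost its call with the unnamed gene as a covariate (-0.061) and with deprived female 5 counted as watered (-0.101), and the female-associated genes without the 4 libraries (0.135). In these 9 cases the adjusted p by camera of limma was 0.051 to 0.52.

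Some other medians kept their call but moved by over 1.5 times. Fatty acid oxidation had 0.114 without the 4 libraries, 0.136 with weights per library, 0.145 and 0.166 with the unnamed gene and the cortex to medulla balance as covariates, and 0.169 without deprived male 7. The tonicity list had -0.115 without the 4 libraries, -0.116 with the cortex to medulla covariate, -0.28 without deprived female 1 and -0.111 without deprived male 7. Proximal tubule had 0.042 without the 4 libraries and 0.039 with weights, with which ribosomal proteins had 0.058 and the nuclear-encoded respiratory chain 0.042. Mitochondrially encoded proteins had 0.405 without deprived female 1, endothelium -0.087 with the unnamed gene, and the unfolded protein response -0.204 with deprived female 5 counted as watered. The cell cycle had -0.183 with that mouse counted so, -0.163 with a filter of 50 and -0.174 without deprived male 4. The female-associated genes had 0.108 with quantile normalization, 0.102 with the cortex to medulla covariate and 0.115 without deprived female 3.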

How the results depend on the processing

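The 2 fits without the 4 libraries that stand apart, and the fit with the unnamed gene as a covariate, were chosen after seeing the data; the others were chosen before. Counts within 1.5 times the reported one held for every comparison with pseudocounts of 0.5 and 5, no filter, a filter of 50, TMM and quantile scaling, edgeR on all libraries, and a prior without the robust option. Among other values with a test, 12913 gene and 7258 list values kept their side of the threshold, 582 and 235 no longer passed, 265 and 149 passed only there, and 1 and 29 changed sign, a change of sign of a value called in neither fit being counted as kept. Of 138 calls of named genes, 95 held in each of the 24 fits that left out 1 library, 56 in every alternative and 131 without the 4 libraries. For each value that moved or changed sign the cause was not tested, except that stricter thresholds leave fewer genes by construction.

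For females, males, the average, the difference between the responses and the genes called in both sexes, DESeq2 gave 364, 157, 562, 46 and 36, and weights per library 1003, 133, 1165, 9 and 56. Leaving out the 4 libraries gave 741, 142, 1230, 9 and 51, and doing so with edgeR 922, 105, 1295, 10 and 49. The unnamed gene as a covariate gave 230 in females, 527 on average, 4 for the difference and 18 in both sexes. An adjusted p under 0.01 left 33, 18 and 87 genes in females, males and on average, and a fold of at least 1.5 left 48, 22 and 39, with 1852 between the sexes with water and 1890 between deprived mice. The balance of cortex to medulla markers as a covariate gave 74 in females, 1005 between the sexes with water and 332 between deprived mice. This balance is itself tied to sex, which limits the reading of the counts between the sexes. Counting deprived female 5 as watered gave 2 in females, 120 on average and 0 in both sexes, and each sex fitted alone gave 11 in males and 7 in both sexes.

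Leaving out 1 library gave 66 to 215 genes in females, 22 to 65 in males, 169 to 330 on average, 0 to 3 for the difference, 8 to 17 in both sexes, 4717 to 6006 between the sexes with water and 4923 to 6138 between deprived mice. The Pearson r ranged from 0 to 0.23. Lists called ranged from 13 to 18 in females, 9 to 16 in males, 11 to 18 on average, 12 to 15 for the difference and 14 to 16 between the sexes. With an estimated correlation camera called 1 list in females, 0 in males, 0 on average, 0 for the difference and 4 between the sexes. Fry called 8, 2, 7, 4 and 21 in these, and weights per library 8 in males.

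Whether the replicate numbers pair the mice was left open, since pairs with different numbers were not scored for comparison. Within a sex, deviations of same-numbered mice correlated from -0.075 to 0.16 by the title's number and from -0.115 to 0.14 by the label code's, over 0.1 in 2 of 11 pairs each. Across the sexes 5 of 22 pairs by the title and 4 of 22 by the code were over 0.1. The highest, 0.45, was that of watered female 6 and deprived male 6, both among the 4 libraries. With the replicate block from the title males had 64 genes and both sexes 25, and with that from the code females had 222 and both sexes 25. Under these blocks the principal cell list had 0.004 in males by either, and by the code ribosomal proteins -0.001 and the respiratory chain -0.008 on average. For the difference the block from the title ended the calls of ribosomal proteins (0.027) and the respiratory chain (0.013), and that from the code those of ribosomal proteins (0.07) and female-associated genes (0.156). Still called there were tonicity (-0.076), fatty acid oxidation (0.146) and endothelium (-0.088) by the title, and fatty acid oxidation (0.18) and the respiratory chain (0.065) by the code.

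Among medians that changed sign, in females ribosomal proteins had 0.095 and the respiratory chain 0.097 with the cortex to medulla covariate, and ribosomal proteins 0.06 with the unnamed gene. In males ribosomal proteins had -0.004 with weights and -0.038 without the 4 libraries, and the respiratory chain -0.021 and -0.049. On average these were -0.032 and -0.047, and -0.044 and -0.053. Principal cell markers had 0.033, 0.049 and 0.016 in males with weights, without the 4 libraries and with the unnamed gene, 0.002, 0.005, 0.003 and 0.004 without watered male 5 or deprived males 4, 5 or 7 (from -0.04 to 0.005 over the 24 fits), and on average -0.041 without a filter and -0.009 with the cortex to medulla covariate. For the difference the respiratory chain had -0.003 without the 4 libraries and -0.005 with the unnamed gene, and thick ascending limb markers 0.079 without the 4. Between the sexes the cortex to medulla covariate, built from markers that include intercalated cells, gave 0.208 for the aldosterone list, called at -0.229 without it, 0.029 for intercalated cells and 0.15 for Podxl. The call of the aldosterone list rested on the preset correlation (camera of limma, adjusted p = 0.0059, and adjusted p = 0.59 with an estimated correlation). Depth limits what can be said of the lowest genes, such as Avpr2 at 3.32 to 6.65.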

Other observations

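The alternatives that leave out the 4 libraries, and the covariate of the unnamed gene, were chosen only after the results were seen; the lists were chosen before the data were examined. Of 20 immediate early genes 2 rose on average, the endothelial flow-response factor Klf2 (0.57 ± 0.12) and Klf4 (0.39 ± 0.10), or 6 adjusted over the list alone (camera of limma, adjusted p = 1.1e-05, and adjusted p = 0.42 with an estimated correlation). Of 15 genes of aldosterone-sensitive transport 2 fell, or 2 adjusted over the list alone, with a median of -0.12 (camera of limma, adjusted p = 0.00071, and adjusted p = 0.42 with an estimated correlation). The 2 called over all genes were Hsd11b2 and Scnn1b, already reported with the collecting duct transport list, which shares them. In the amino acid response 2 of 14 members rose, among them Mthfd2, a mitochondrial folate enzyme (0.43 ± 0.11), or 3 with 1 lower adjusted over the list alone (camera of limma, adjusted p = 0.074). In females the NRF2 list was lower, with 1 of 12 fallen, the quinone reductase Nqo1 (-0.50 ± 0.10), or 2 adjusted over the list alone (camera of limma, adjusted p = 0.0012, and adjusted p = 0.068 with an estimated correlation). The Nqo1 call was lost without deprived female 5 (limma adjusted p = 0.061), while Klf4 passed in 9 and Mthfd2 in 5 of the 24 fits that left out 1 library. Renin, Ren1, the enzyme that starts angiotensin formation, had 0.21 ± 0.12 on average (limma adjusted p = 0.46), and 0 of 11 genes of its system passed, or 0 adjusted over the list alone (camera of limma, adjusted p = 0.55).

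Heat shock genes had a median of 0.12 in females and -0.11 in males (camera of limma, adjusted p = 1.7e-05 and 0.033, and adjusted p = 0.14 and 0.65 with an estimated correlation). Over all genes 0 of 19 rose in females, or 5 adjusted over the list alone, and in males Dnaja1 fell by 0.30 on the log2 scale, or 3 genes adjusted over the list alone. Genes of the unfolded protein response had a median of 0.14 in females, with 0 of 15 past the test or 4 higher adjusted over the list alone, and -0.18 in males, with 0 or 4 lower (camera of limma, adjusted p = 1.7e-05 and 1.3e-05, and adjusted p = 0.31 and 0.47 with an estimated correlation). Cell cycle genes had 0.34 in females, with 0 of 18 past the test, or 0 adjusted over the list alone (camera of limma, adjusted p = 1.7e-05, and adjusted p = 0.17 with an estimated correlation). Fatty acid oxidation genes had -0.17 in females, with 0 of 20, or 1 lower adjusted over the list alone (camera of limma, adjusted p = 2.9e-05, and adjusted p = 0.32 with an estimated correlation). The 13 mitochondrially encoded protein genes had -0.21 in females, with 0 past the test, or 0 adjusted over the list alone (camera of limma, adjusted p = 0.00022, and adjusted p = 0.14 with an estimated correlation).

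On average over the sexes, markers of intercalated cells had a median of -0.14, with 1 of 10 fallen, or 4 lower and 1 higher adjusted over the list alone (camera of limma, adjusted p = 0.033, and adjusted p = 0.42 with an estimated correlation). Genes of vitamin D, calcium and phosphate handling had -0.10, with 0 of 12 past the test, or 0 adjusted over the list alone (camera of limma, adjusted p = 0.011, and adjusted p = 0.25 with an estimated correlation). In males markers of the distal convoluted tubule had -0.26, with 0 of 7 past the test, or 2 lower adjusted over the list alone (camera of limma, adjusted p = 0.025, and adjusted p = 0.47 with an estimated correlation).

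The lists that remain did not pass on average by camera of limma. Hypoxia genes had 2 of 15 fallen, or 2 with 1 higher adjusted over the list alone, and a median of 0.02 against a mean of -0.04 (camera of limma, adjusted p = 0.7). Tubular injury genes had 1 of 12 risen, or 1 adjusted over the list alone (camera of limma, adjusted p = 0.057). In females this list was called higher, with a median of 0.13, 0 of 12 past the test and 0 adjusted over the list alone (camera of limma, adjusted p = 0.034, and adjusted p = 0.43 with an estimated correlation). Thick ascending limb markers had 1 of 8 risen, or 2 adjusted over the list alone, with a median of -0.03 against a mean of 0.03 (camera of limma, adjusted p = 0.55). With 0 past the test, and 0 adjusted over the list alone, gluconeogenesis had an adjusted p of 0.73 by camera of limma, interferon response 0.64, leukocytes 0.082 and urothelium 0.35. Adipocyte, adrenal and erythrocyte markers likewise had 0, with adjusted p-values of 0.39, 0.7 and 0.056 by camera of limma.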
